A study of Homo sapiens with 8 samples.

How the data were processed

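Total RNA depleted of rRNA was sequenced from HCT116 cells and a MED12 E33Q knock-in derivative, without treatment (0 h) or after 24 h with 5 ng/ml IFN-γ, in 8 libraries, 2 per group. According to the submitters' processing notes, reads were trimmed with Trimmomatic and quantified with kallisto against GRCh38. The versions of these tools, the transcript annotation and the amount of spike-in RNA added are not given in the sources used here. The deposited table holds estimated counts per Ensembl gene ID from the authors, with 40295 gene IDs and 63 ERCC spike-ins, and 58.3% of its nonzero values are not whole numbers (tolerance 1e-06). Every column was mapped to a library by its label. Gene names, positions, GC content and length came from GENCODE release 29 on GRCh38, which named 35583 IDs. The other 4712 were tested without a name. They held 2.23 to 2.46% of the counts of an untreated and 2.97 to 3.05% of those of a treated library. Of 15137 IDs with over 100 counts, 910 had counts identical to those of another ID, so reads shared between near-identical genes may be counted more than once.

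The estimated counts were rounded to whole numbers, and the ERCC spike-ins were left out of all tests. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 16519, and libraries were scaled by the trimmed mean of M-values (TMM), with factors from 0.86 to 1.134. Group was the only factor of the model, and each contrast used all 8 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05; common dispersion 0.0415, a coefficient of variation of 20.4%). The contrasts were the IFN-γ response in each line, the knock-in against the wild-type line without and with IFN-γ, the difference between the responses, the mean response and the mean line difference. Standard errors were the size of the log2 fold change divided by the square root of F. Values in CPM are counts relative to the library total after TMM scaling. A fold against a group at 0 was bounded with a floor of 3 counts per library, and a group with 1 to 3 counts was given as a ratio with a 95% counting interval, which covers counting error only.

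Curated lists of 661 genes in 29 groups, written from general knowledge before the data were examined, were tested with camera from limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry, where at least 5 members were tested. Counts of list members are over all tested genes unless given as adjusted over the list alone. The size of the response was the median, over genes changed by 2-fold or more in the mean response, of the knock-in minus the wild-type log2 fold change. These genes were chosen anew in each alternative.

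Genes were named by a rule set in advance. For each contrast these were the 10 largest rises and 10 largest falls among called genes with a symbol and a mean of at least 5 CPM in a group compared and, for pairwise contrasts, no overlap between replicates. For each list called by camera or with at least 3 called members, the 4 called members with the largest change were added, along with a fixed set that included MED12, MED13, CDK8, CDK19, CCNC, IRF1, IRF9, SOCS1, CIITA, CXCL10, GBP1, IDO1, CD274, HLA-B, TAP1, CD74, MX1, IFIT1, MYC, CDKN1A and AXIN2. Some genes that the rule takes are not reported here, those at the end of these orders were left out for length, and a gene named in a comparison may be given in another.

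The alternatives tried were DESeq2's size factors and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter beyond a total above 0, at least 50 counts in at least 2 libraries, the replicate number as a block, only the groups compared, glmTreat against 1.5-fold, exclusion of mitochondrial, histone and small RNA genes, and each library left out in turn. Chosen after the data were seen were removal of each library's trend on GC content and length (loess, span 0.3, as an offset; GC content was known for 92.4% of tested genes), scaling to ERCC spike-in totals, and exclusion of libraries by immunoglobulin counts. The fit was tested on simulated data made from these libraries, in which known changes were planted. At each fold, 94 to 99 of 16148 to 16162 tested genes were changed, with no GC trend and independent noise for each gene. More genes were called in the real responses and line differences, so the recoveries given next hold for this simulated setting only. Recovery of 2-fold and 4-fold changes was 42.7 and 77.7% for the wild-type response, 40.6 and 77.7% for the knock-in response, 46.9 and 77.7% for the untreated line difference, 48 and 79.8% for that with IFN-γ, 15.5 and 66.7% for the difference between responses, 63.5 and 85.1% for the mean response and 69.4 and 88.3% for the mean line difference, with 10 to 18 unchanged genes called. The counts of called genes were also compared over all 35 splits of the libraries into 4 and 4 and, with treatment as a term, over the 18 of them that keep treatment balanced.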

Results

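The series compared HCT116 cells, a human colorectal cancer line, with a CRISPR-Cas9 knock-in derivative that carries the E33Q change in MED12, a subunit of the Mediator kinase module. Cells were untreated (0 h) or treated for 24 h with 5 ng/ml interferon-gamma (IFN-γ). Every untreated library is labelled 0 h and every treated one 24 h, so time in culture cannot be told apart from IFN-γ. With 2 replicates in each of 4 groups there were 8 libraries of rRNA-depleted total RNA with ERCC spike-in RNAs. Estimated counts per library summed to 22500317 and 22940906 in untreated wild-type and 23432640 and 22353370 in treated wild-type cells. They summed to 20901909 and 28045842 in untreated and 24150306 and 22235645 in treated knock-in cells. Between 14756 and 15787 genes per library had at least 10 counts, and 16519 genes were tested. Only 1 knock-in line was named, so a difference between the lines cannot be divided between the E33Q change and clonal differences. The replicates may be technical, and every p-value here measures spread between these samples.

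MED12 itself (chromosome X, 71118556 to 71142454 on GRCh38, GENCODE release 29) was detected in all 8 libraries. Its normalised counts (CPM) were 23.11 and 14.17 in untreated wild-type, 34.32 and 28.32 in treated wild-type, 12.92 and 11.16 in untreated knock-in and 33.32 and 30.06 in treated knock-in cells. E33Q is a point change, so the RNA level does not check the genotype. MED12 was not called between the lines without treatment (log2 fold change −0.63 ± 0.24 standard error, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.123, n = 2 per group) or with it (0.02 ± 0.23, adjusted p = 0.987). The untreated difference depended on single libraries, at −0.94 without untreated wild-type library 2 and −0.24 without untreated wild-type library 1. MED12 rose with IFN-γ in knock-in cells (1.40 ± 0.24, adjusted p = 0.00105). This rise was 0.40 (adjusted p = 0.0638) once a trend with transcript GC content and length was removed, and 0.87 (0.0821) under spike-in scaling. The rise in wild-type cells was 0.75 ± 0.23 (adjusted p = 0.0303), but −0.08 under spike-in scaling and 0.03 with the trend removed. It was not called without untreated wild-type library 2 (0.44, adjusted p = 0.124), treated wild-type library 1 (0.60, 0.173) or treated wild-type library 2 (0.88, 0.058). Among its kinase module partners, CDK8 was not called with IFN-γ in wild-type (−0.12, adjusted p = 0.532) or knock-in cells (−0.13, 0.494), nor was CDK19 (0.10, 0.687; −0.13, 0.558) or MED13 (0.21, 0.247; −0.11, 0.534). With the trend removed, MED13 was called higher in wild-type (0.38, adjusted p = 0.00687) and knock-in cells (0.30, 0.0161). Spike-in scaling called it lower in wild-type (−0.57, adjusted p = 0.017) and knock-in cells (−0.64, 0.00998). It also called CDK8 lower in wild-type (−0.92, 0.00563) and knock-in cells (−0.66, 0.0325), but not CDK19. Cyclin C (CCNC) fell in wild-type (−1.15 ± 0.15, adjusted p = 0.000719) and knock-in cells (−1.48 ± 0.15, 0.000177), with −0.36 and −0.42 left after the trend was removed. MED13L, a paralogue of MED13, rose in wild-type (0.70 ± 0.13, adjusted p = 0.00333; 246.1 and 218.5 to 374.2 and 378.5 CPM) and knock-in cells (0.85 ± 0.13, 0.000709; 143.5 and 119.7 to 233.3 and 240.1 CPM). Under spike-in scaling its changes were −0.12 and 0.32, neither called.

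The composition of the libraries moved with treatment. The mean transcript GC content of the counts was 47.05 and 45.87% in untreated wild-type, 45.65 and 45.77% in untreated knock-in, and between 48.33 and 48.52% in the treated libraries. Ribosomal protein mRNAs took 8.37 to 9.65% of counts without and 4.92 to 6.05% with IFN-γ. ERCC spike-ins made up 0.119 ± 0.013% (mean ± SD, n = 2) of counts in untreated and 0.249 ± 0.031% in treated wild-type cells, against 0.139 ± 0.002% and 0.263% in the knock-in line. Scaling to the spike-ins shifted the log2 fold changes of all genes by a median of −0.80 for the wild-type response, −0.53 for the knock-in response, −0.33 and −0.06 for the line difference without and with IFN-γ and 0.27 for the difference between responses. It shifted the mean response by −0.67 and the mean line difference by −0.19. The median of all genes went from 0.08 to −0.72 for the wild-type and from 0.12 to −0.41 for the knock-in response. All changes below are therefore relative to the other genes of a library, under trimmed-mean (TMM) scaling unless another is named.

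**Figure D1:**
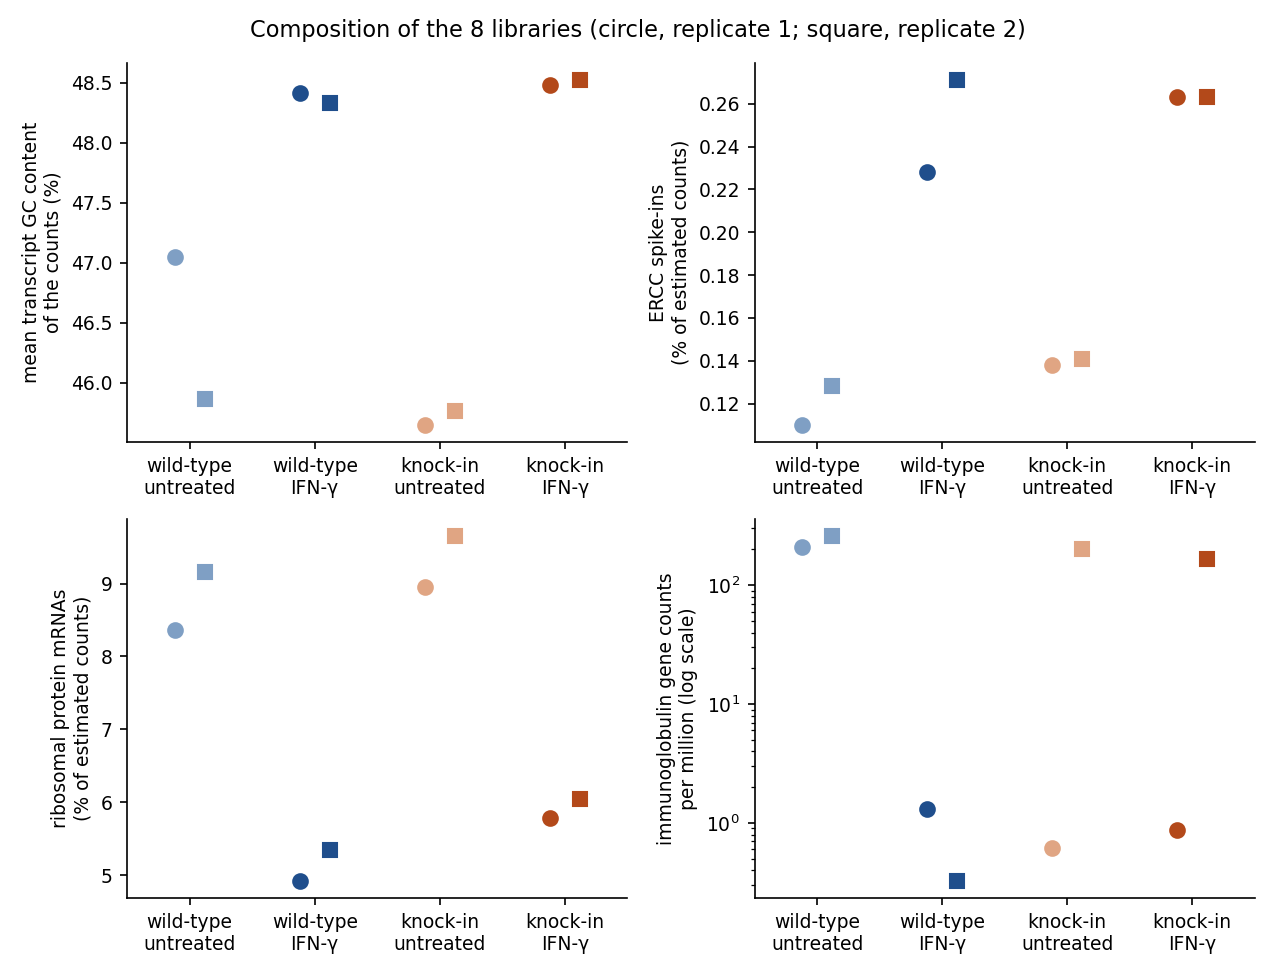
Mean transcript GC content (%), ERCC spike-ins and ribosomal protein mRNAs (% of estimated counts) and immunoglobulin gene counts (CPM, log axis) in each of the 8 libraries, grouped by line and treatment, with circles for replicate 1 and squares for replicate 2. ERCC spike-ins lay at 0.11 to 0.141% without and 0.228 to 0.271% with IFN-γ, and immunoglobulin counts lay between 165 and 258 CPM in 4 libraries and at 1.3 or below in the other 4.

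The first comparison asked which genes differed between treated and untreated wild-type cells. The interferon programme rose strongly. IDO1, which breaks down tryptophan (chromosome 8, 39902275 to 39928444), went from 0 counts to 9.932 ± 0.726 CPM (mean ± SD, n = 2), at least 69-fold. GBP1, a guanylate-binding protein of antimicrobial defence (chromosome 1, 89052319 to 89065360), rose from 0.05 to 90.21 ± 0.804 CPM, a ratio of 1880 (95% counting interval 521 to 15500). The apolipoprotein L genes APOL3 (7.62 ± 0.28), APOL6 (7.58 ± 0.20; 2.271 ± 0.613 to 432.9 ± 13.6 CPM) and APOL1 (5.51 ± 0.24) rose. LGALS9, which encodes galectin-9, rose by 6.48 ± 0.61 (10.76 without untreated wild-type library 2). The transcription factors ETV7 (6.12 ± 0.23) and BATF2 (5.84 ± 0.49) rose with IFIT3 (5.82 ± 0.23) and EPSTI1 (5.45 ± 0.27), interferon-stimulated genes. IRF1, the transcription factor that carries much of the response to IFN-γ (chromosome 5, 132481609 to 132490798), went from 11.96 ± 2.32 to 348.7 ± 17.3 CPM (4.86 ± 0.17, adjusted p = 9.83e-07).

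Genes of antigen presentation rose with them in wild-type cells. NLRC5, the activator of MHC class I genes, rose by 4.94 ± 0.21 (edgeR quasi-likelihood, adjusted p = 1.84e-06), the immunoproteasome subunit PSMB9 by 4.57 ± 0.32 (4.18e-05), the peptide transporter TAP1 by 3.91 ± 0.27 (3.51e-05) and HLA-B by 1.57 ± 0.17 (0.000423). CD274, which encodes PD-L1, rose by 2.40 ± 0.34 (adjusted p = 0.00098), IRF9 by 2.31 ± 0.20 (0.00014) and IFIT1 by 1.10 ± 0.19 (0.00237). MX1 (0.50, adjusted p = 0.241), the feedback inhibitor SOCS1 (1.43, 0.0545) and CDKN1A (0.31, 0.0817) were not called. AXIN2, a Wnt target, rose by 0.87 ± 0.17 (adjusted p = 0.00376). CIITA, the activator of MHC class II genes, rose by 1.66 ± 0.37 (adjusted p = 0.00779), but by 1.06 without untreated wild-type library 1. It was not called without treated wild-type library 1 (1.53, adjusted p = 0.0507) or with the GC trend removed (0.70, 0.274). MYC rose by 0.63 ± 0.19 (adjusted p = 0.0269) under TMM and fell by 0.21 under spike-in scaling, with 0.35 left without untreated wild-type library 2 and no call without treated wild-type library 1 (0.62, adjusted p = 0.114) or 2 (0.64, 0.1). CXCL10 and HLA-DRA had 0 counts in every library. MHC region genes have close relatives that can share reads, so their levels are uncertain. Whether some of their reads were assigned to IDs without a name was not tested.

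Ribosomal protein mRNAs fell in wild-type cells with IFN-γ, among them RPS27 (−1.62 ± 0.14), RPS13 (−1.53 ± 0.15), RPS18 (−1.51 ± 0.15) and RPL27 (−1.39 ± 0.13). So did CCNG1 (−1.70 ± 0.16), a p53 target, and the cell cycle genes CCNE2 (−1.63 ± 0.13), CCNB1 (−1.37 ± 0.19), CDK1 (−1.36 ± 0.16) and PCNA (−1.36 ± 0.19). These falls ran alongside the GC shift of the libraries. With the trend removed, RPS27 (−0.23, adjusted p = 0.383) and CDK1 (−0.30, 0.0689) were not called, while CCNE2 (−0.89, 4e-04) and CCNG1 (−0.87, 0.000311) were. Of 36 ribosomal protein mRNAs, 29 were called lower and 1 higher with the trend removed.

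The largest falls in wild-type cells belonged to immunoglobulin and plasma cell genes. JCHAIN, the joining chain of secreted antibody (chromosome 4, 70655541 to 70681817), fell at least 1350-fold from 160.3 ± 3.71 CPM, IGKC at least 688-fold, IGHA1 at least 635-fold, IGKV3D-20 at least 500-fold and IGHA2 at least 109-fold. TXNIP (at least 68.7-fold), ARHGAP30 (at least 60.2-fold) and the leukocyte integrin ITGA4 (at least 45.1-fold) also reached 0 counts. CD48 fell to a ratio of 0.00296 (95% counting interval 7.46e-05 to 0.0166), and the plasma cell factor IRF4 fell by 7.45 ± 2.19 (adjusted p = 0.0249). The immunoglobulin signal stood at 211 and 258 CPM in untreated wild-type, 200 in untreated knock-in library 2 and 165 in treated knock-in library 2, and at 1.3 or below in the other libraries. In the knock-in line these genes therefore followed single libraries and not treatment. In wild-type cells the signal was in both untreated libraries and in neither treated one, so it enters the wild-type response in full. JCHAIN (adjusted p = 0.0406), at 162.9 and 157.6 CPM in untreated against 0 in both treated wild-type libraries, lost its call without untreated wild-type library 1 (0.0717) or 2 (0.102) or treated wild-type library 1 (0.146) or 2 (0.139). With 1 library left in a group its levels stayed as far apart, so its lost calls do not mark a smaller difference. The others lost theirs without untreated library 2 or either treated library (adjusted p from 0.0763 to 0.165, IRF4 at −11.71 without treated library 1), all but IRF4 also without untreated library 1. CD74, the invariant chain of MHC class II, moved with this signal (−3.92 ± 1.39, adjusted p = 0.0505). In the knock-in libraries without the signal, CD74 stood at 0.111 CPM in untreated library 1 and 4.98 CPM in treated library 1. No untreated wild-type library was without the signal, so the CD74 response of wild-type cells cannot be read.

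In all, 6256 genes were called in wild-type cells, 2821 higher and 3435 lower, of which 918 rose and 1466 fell by 2-fold or more. This count includes genes of the immunoglobulin signal, which coincided with treatment in wild-type cells. Under spike-in scaling the split was 233 higher and 6745 lower. With the GC trend removed 3970 genes were called. The count fell to 3266 without treated wild-type library 1 and 3754 without treated wild-type library 2. A test on simulated data, with fewer changed genes than were called here, recovered 42.7% of 2-fold and 77.7% of 4-fold changes.

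Tested as lists in wild-type cells, the IFN-γ core response had a median log2 fold change of 2.87, with 44 of 50 genes higher and 1 lower (46 and 1 adjusted over the list alone; camera, adjusted p = 7.47e-25, and adjusted p = 0.00591 with an estimated correlation). Type I interferon-stimulated genes had a median of 2.07, with 37 of 47 higher (camera, adjusted p = 3.94e-15, and adjusted p = 0.0451 with an estimated correlation). MHC class I genes had a median of 2.46 and 17 of 21 higher (camera, adjusted p = 5.72e-09, but adjusted p = 0.162 with an estimated correlation). Ribosomal protein mRNAs had a median of −1.08, with 31 of 36 lower (34 adjusted over the list alone; camera, adjusted p = 4.04e-14, but adjusted p = 0.479 with an estimated correlation), and −0.55 with the GC trend removed. Replication-dependent histones, whose near-identical mRNAs share reads, had a median of −0.75 with 7 of 14 lower. Camera gave adjusted p = 0.027, but adjusted p = 0.538 with an estimated correlation. With the GC trend removed the median was 0.11, with 3 genes called lower and 1 higher. The histone call was lost without untreated wild-type library 2 (−0.60, adjusted p = 0.0851) or treated wild-type library 1 (−0.50, 0.155).

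The other lists were not called in wild-type cells by camera. Adjusted p was 0.0507 for JAK-STAT components (median 0.60 under TMM and −0.23 under spike-in scaling) and for mitochondrially encoded mRNAs (−0.60, but 0.24 with the GC trend removed). It was 0.0846 for caspases and death receptors and 0.0876 for cell cycle genes (median −0.30, 19 of 44 lower and 7 higher), each 0.0124 with the trend removed. Housekeeping genes stood at 0.114, immediate early genes at 0.111, fatty acid synthesis at 0.173, NF-kB targets at 0.218, cholesterol biosynthesis and heat shock proteins at 0.288 and mesenchymal markers (median 0.30, mean −0.10) at 0.298. Wnt targets (median 0.44, mean −0.05) stood at 0.381, p53 targets (median 0.00, mean −0.17) and the unfolded protein response at 0.403, intestinal epithelial genes at 0.412, Mediator core subunits at 0.469 and glycolysis at 0.487. It was 0.525 for endothelial markers, 0.557 for hypoxia genes, 0.582 for the Mediator kinase module, 0.7 for fibroblast markers, 0.847 for leukocyte markers, 0.973 for MYC targets and 0.979 for MHC class II genes. The MHC class II list had a median of −0.15 and a mean of −1.09. A wild-type response of genes that move with the immunoglobulin signal, such as CD74, cannot be told from that signal.

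The second comparison asked the same of the knock-in line. IDO1 went from 0 counts to 12.95 ± 0.186 CPM (n = 2), at least 89.3-fold. GBP1 rose by 9.26 ± 0.31 to 105.1 ± 4.41 CPM, and the peptide transporter SLC15A3 at least 42.8-fold. APOL3 (7.55 ± 0.27), APOL6 (6.99 ± 0.19), LGALS9 (6.82 ± 0.59), APOL1 (6.32 ± 0.25), NLRC5 (6.12 ± 0.23) and BATF2 (6.03 ± 0.49) rose. CASP1, the inflammasome caspase, rose with a ratio of 90 (95% counting interval 30.5 to 439; log2 value 6.42, and 10.22 without untreated knock-in library 2). IRF1 rose by 4.92 ± 0.17 to 343.8 ± 11.8 CPM (edgeR quasi-likelihood, adjusted p = 9.62e-07), TAP1 by 4.27 ± 0.27 (1.99e-05), CD274 by 2.17 ± 0.34 (0.000715), IRF9 by 2.04 ± 0.19 (0.000151) and HLA-B by 1.63 ± 0.17 (0.000188). SOCS1 (3.47 ± 0.59, adjusted p = 0.00109), CIITA (2.05 ± 0.38, 0.00168) and MX1 (1.34 ± 0.32, 0.00641) were called here, CIITA not with the GC trend removed (0.98, 0.121). IFIT1 was not called (0.26, 0.275).

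MYC rose in the knock-in line from 98.73 ± 8.91 to 262.2 ± 2.87 CPM (1.41 ± 0.19, edgeR quasi-likelihood, adjusted p = 0.000396). The transcription factors KLF4 rose by 1.60 ± 0.25 (0.000658), EGR1 by 1.47 ± 0.18 (0.000247) and FOSB by 1.48 ± 0.22 (0.000572). AXIN2 rose by 1.04 ± 0.17 (adjusted p = 0.000915) and CDKN1A by 0.58 ± 0.13 (0.00421, but 0.04 with the GC trend removed). Among falling genes, SCO2 went to 0 counts (at least 56.1-fold). This is uncertain because a second gene ID shares its name, and the call was lost without untreated knock-in library 1 (adjusted p = 0.0664) or 2 (0.074) or treated knock-in library 1 (0.11) or 2 (0.102). The selenium carrier SELENOP fell by 2.65 ± 0.30 (adjusted p = 0.000203), the adhesion protein FLRT3 by 2.56 ± 0.45 (0.00129), and the nucleosome-binding HMGN5 by 2.54 ± 0.35 (0.000396). The pseudogene HNRNPA1P48, which can share reads with its parent gene, fell by 2.47 ± 0.42 (0.00106), WDR63 by 2.46 ± 0.35 (0.00045) and CCDC126 by 2.36 ± 0.31 (0.000331). KITLG, the ligand of the KIT receptor, fell from 3347 ± 650 to 672 ± 37.9 CPM (−2.32 ± 0.18, adjusted p = 6.48e-05). The cell cycle genes CCNE2 (−1.88 ± 0.13), CDK1 (−1.86 ± 0.16) and CCNB1 (−1.69 ± 0.19), with CCNG1 (−2.10 ± 0.17), fell as in wild-type cells.

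In all, 8613 genes were called in the knock-in line, 4356 higher and 4257 lower (2341 and 2235 by 2-fold or more), and 616 higher and 5476 lower under spike-in scaling. With the GC trend removed 4992 were called. Of the simulated changes, 40.6% of 2-fold and 77.7% of 4-fold ones were recovered. As lists, the IFN-γ core response had a median of 2.85 with 45 of 50 higher and 2 lower (camera, adjusted p = 1.22e-18, and adjusted p = 0.0104 with an estimated correlation). Type I genes had a median of 2.28 with 38 of 47 higher and 1 lower (camera, adjusted p = 7.57e-12, but adjusted p = 0.0716 with an estimated correlation). MHC class I genes had a median of 1.95 with 16 of 21 higher and 1 lower (17 and 1 adjusted over the list alone; camera, adjusted p = 2.07e-06, but adjusted p = 0.288 with an estimated correlation). Ribosomal protein mRNAs had a median of −1.07 with 32 of 36 lower (33 adjusted over the list alone; camera, adjusted p = 1.31e-10, but adjusted p = 0.514 with an estimated correlation), and −0.49 with the GC trend removed. Immediate early genes had a median of 0.61 with 12 of 24 higher and 2 lower (camera, adjusted p = 0.0162, but adjusted p = 0.586 with an estimated correlation and 0.276 with the GC trend removed). Histones had a median of −0.86 with 7 of 14 lower (camera, adjusted p = 0.031, but adjusted p = 0.586 with an estimated correlation). With the trend removed the median was −0.10, and 3 of the 14 were called lower. The list was not called without untreated knock-in library 2 (−0.57) or treated knock-in library 1 (−0.82).

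Every other list had a camera adjusted p above 0.05 in the knock-in line. Cell cycle genes (median −0.46, 24 of 44 lower and 14 higher) and caspases stood at 0.0841 (0.00488 and 0.00805 with the GC trend removed), JAK-STAT components at 0.0993, mesenchymal markers at 0.119, Wnt targets and housekeeping genes at 0.132, NF-kB targets at 0.166, cholesterol biosynthesis at 0.182, and heat shock proteins at 0.189. Glycolysis stood at 0.251, MHC class II genes at 0.289 and Mediator core subunits, with 9 of 26 higher and 14 lower, at 0.319. MYC targets, fatty acid synthesis and mitochondrially encoded mRNAs stood at 0.397 (the last at a median of −0.29, but 0.93 with 6 of 11 genes higher and adjusted p = 0.00868 with the GC trend removed), p53 targets at 0.399, the unfolded protein response (median 0.08, mean −0.14) at 0.537 and intestinal epithelial genes at 0.606. Leukocyte markers stood at 0.673, endothelial markers at 0.678, fibroblast markers at 0.757, hypoxia genes at 0.759 and the Mediator kinase module (median −0.11, mean 0.13) at 0.768.

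The responses of the lines overlapped. Both lines raised 2478 genes (743.9 expected from the counts) and lowered 3212 (885.2 expected), and 3 genes went opposite ways (Pearson correlation 0.515). Averaged over the lines, 9665 genes were called, 5020 higher and 4645 lower, of which 1622 rose and 1917 fell by 2-fold or more. Under spike-in scaling the split was 557 higher and 7162 lower. Recovery of simulated changes was 63.5% at 2-fold and 85.1% at 4-fold. Part of the shared response followed base composition. The correlation of a gene's GC content with its change (Spearman, 15270 genes) was 0.49 in wild-type and 0.64 in knock-in cells. The median change ran from −0.72 in the tenth of genes with the lowest GC to 0.46 in that with the highest in wild-type cells, and from −1.04 to 0.91 in knock-in cells. With the trend removed, correlations with GC content of 0.13 in wild-type and 0.11 in knock-in cells were left. In that fit 1426 genes rose in both lines (294.8 expected) and 1678 fell in both (304.8 expected).

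**Figure D2:**
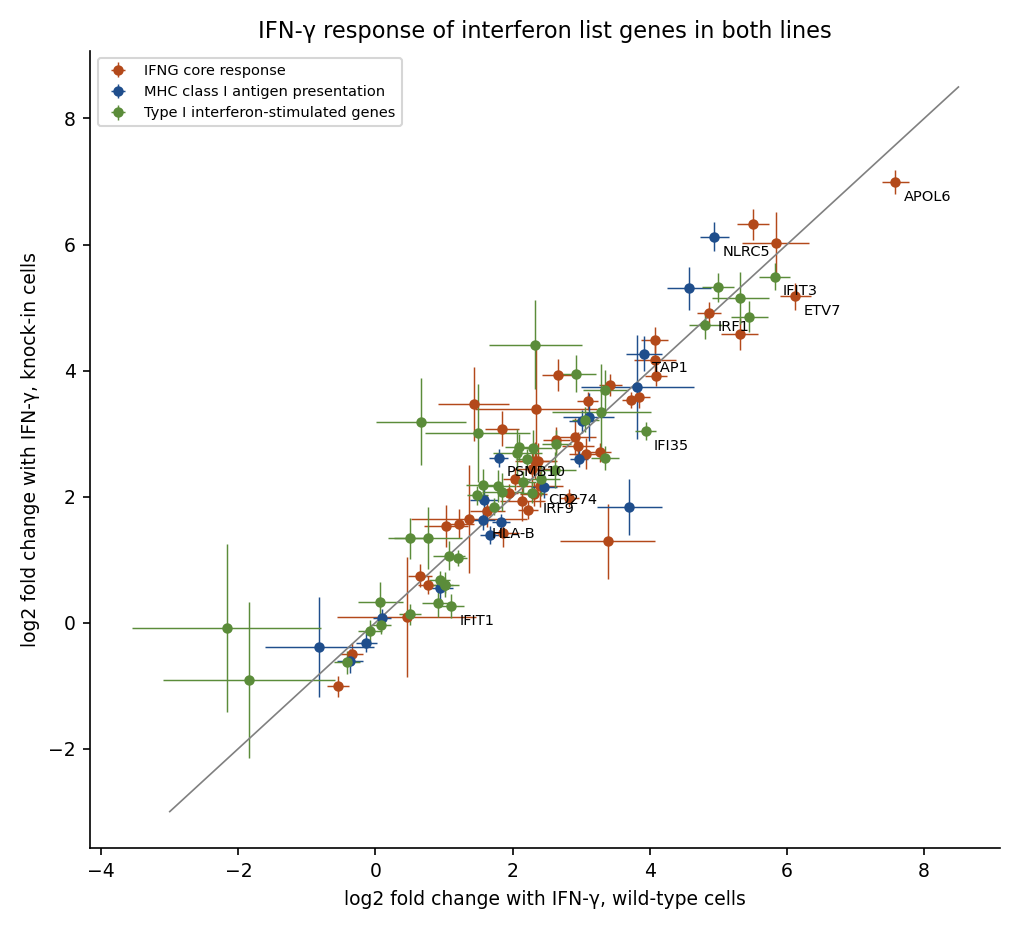
Log2 fold change with IFN-γ in wild-type (horizontal axis) against knock-in cells (vertical axis) for 106 genes of the interferon lists that reached 0.25 CPM in an untreated library of each line, with bars of 1 standard error and a line of equal response. APOL6 (7.58 and 6.99) and IRF1 (4.86 and 4.92) lay near the line, IFIT1 (1.10 and 0.26) below it and NLRC5 (4.94 and 6.12) above it.

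The third comparison asked whether the lines responded differently. No gene was called in the difference between responses (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 0 of 16519), where 1119 had an unadjusted p below 0.05. The knock-in minus wild-type difference was −0.84 ± 0.27 for IFIT1, an interferon-induced antiviral gene, 0.77 ± 0.27 for MYC, 2.04 ± 0.77 for SOCS1 and 0.83 ± 0.45 for MX1 (adjusted p = 0.688 each, not called). It was 0.06 ± 0.21 for IRF1 (adjusted p = 0.947), 0.06 ± 0.24 for HLA-B (0.95), −0.22 ± 0.47 for CD274 (0.898) and 0.36 ± 0.35 for TAP1 (0.762), which does not show equal responses. Adjusted over the list alone, 2 genes were lower in the IFN-γ core list, among them SERPING1 (0.0196, with 0 counts in untreated wild-type), and 1 among JAK-STAT components. NLRC5 (1.18 ± 0.29, 0.028) and PSMB10 (0.82 ± 0.19, 0.028) were higher in the MHC class I list. VIM (2.69 ± 0.54, 0.0152) was higher among mesenchymal markers, but moved with the immunoglobulin signal.

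Other tools called few genes in this difference. DESeq2 called 4, limma-voom 0. With no filter on low counts, edgeR called 267, 189 higher and 78 lower. With a replicate block within line it called 27, 25 higher and 2 lower. The 4 of DESeq2 were VIM (2.68, adjusted p = 0.000696), the transcript AC008878.3 and a pair of gene IDs without a name in the annotation. All lie outside the naming rule as applied to this difference and were chosen after their values were seen. Without untreated wild-type library 2 the 2 genes called were AC034102.2 (adjusted p = 0.0374) and AC106886.5 (0.0374), and without treated wild-type library 1 they were MDC1 (0.0254) and an unnamed ID, chosen in the same way. In a simulation, 15.5% of 2-fold and 66.7% of 4-fold differences of responses were recovered, so differences near 2-fold may mostly have been missed.

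Genes raised by 2-fold or more on average rose further in the knock-in line, by a median of 0.361 (quartiles 0.046 to 0.595; 1622 genes, medians 1.111 and 1.44; camera p = 1.67e-08, but p = 0.314 with an estimated correlation), with 23.2% of them rising less. The excess was not in proportion to the response. The major axis of knock-in on wild-type change over these genes had a slope of 0.596. The IFN-γ core list had a median difference of −0.11 and a mean of −0.29, and was not called. Lowered genes fell further, by a median of −0.213 (quartiles −0.397 to −0.036; 1917 genes, medians −1.163 and −1.358; camera p = 9.24e-11, but p = 0.395 with an estimated correlation), but the difference was 0.05 under spike-in scaling. The excess among raised genes was 0.06 and that among lowered genes −0.01 without untreated wild-type library 1, neither called by camera. That is the untreated library with the highest GC content. The excess was 0.60 for raised genes without untreated knock-in library 1, and −0.42 for lowered genes without untreated wild-type library 2. With the GC trend removed the medians were 0.061 (799 genes) and −0.094 (303 genes), neither called by camera. The correlation of GC content with the difference between responses went from 0.5 to 0.01.

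With the GC trend removed, MYC targets were called in the difference between responses (median 0.16, camera, adjusted p = 0.0349). Before its removal they were the 1 list called, with a median of 0.19 and a mean of 0.29 (camera, adjusted p = 0.0403, but adjusted p = 0.684 with an estimated correlation and 0.0809 with fry). The call was lost without untreated wild-type library 2 (0.18, adjusted p = 0.25), treated wild-type library 1 (0.20, 0.256), untreated knock-in library 1 (0.24, 0.0599) or treated knock-in library 1 (0.20, 0.0718) or 2 (0.26, 0.101). The IFN-γ core response (adjusted p = 0.517), MHC class I (0.863) and type I interferon-stimulated genes (0.863) were not called, nor were mitochondrially encoded mRNAs (0.25, 0.217, but 0.48 and 0.0349 with the GC trend removed).

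**Figure D3:**
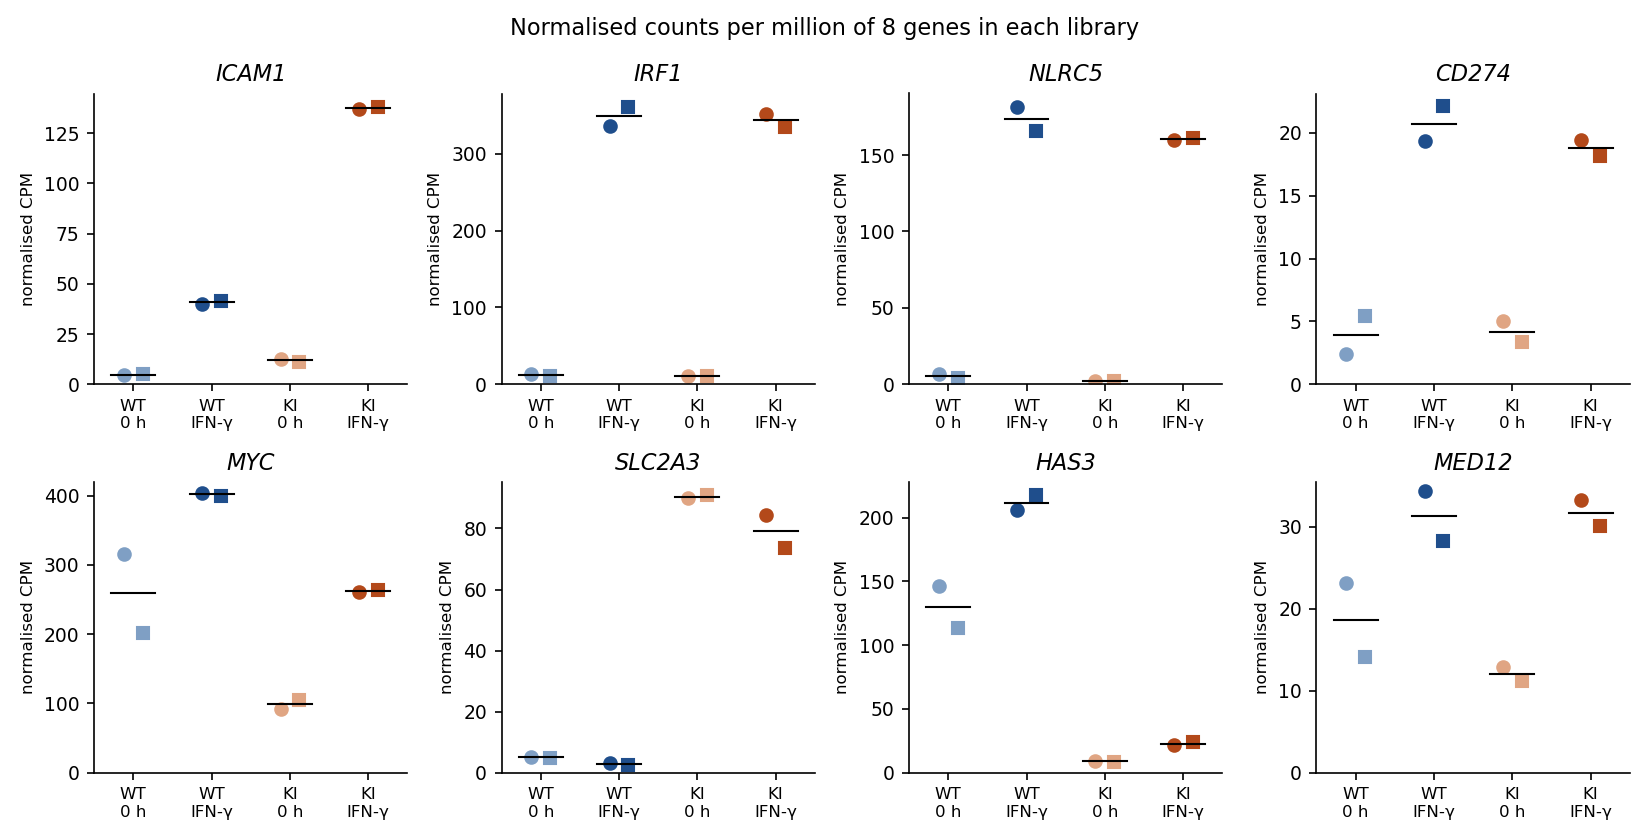
Normalised counts (CPM) of ICAM1, IRF1, NLRC5, CD274, MYC, SLC2A3, HAS3 and MED12 in each library, by line and treatment (0 h or 24 h IFN-γ; circle replicate 1, square replicate 2, bar the group mean). ICAM1 reached 40.76 CPM in treated wild-type and 137.5 CPM in treated knock-in cells, and SLC2A3 stood at 5.027 and 90.36 CPM in the untreated lines.

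The fourth comparison asked how the lines differed without treatment. The knock-in line expressed genes that were almost silent in wild-type cells. ANKRD1, a stretch and YAP-responsive gene (chromosome 10, 90912096 to 90921276), rose from 0.094 to 30.51 ± 0.165 CPM (8.24 ± 0.46, adjusted p = 2.38e-05, n = 2). The matrix protein SPARC was higher by 6.23 ± 0.55 (0.000691). MAGEB1, a cancer-testis antigen, went from 1.161 ± 0.342 to 73.65 ± 9.99 CPM (5.99 ± 0.25, adjusted p = 6.49e-06), and the glucose transporter SLC2A3 from 5.027 ± 0.169 to 90.36 ± 0.623 CPM (4.17 ± 0.17, 6.49e-06). HAS2, a hyaluronan synthase, was higher by 5.82 ± 0.89 (10.42 without untreated wild-type library 1), FLRT3 by 5.49 ± 0.55, the mucin MUC13 by 5.30 ± 0.57 and the vessel factor ANGPT2 by 4.98 ± 0.25. GALNT4 was at least 44.4-fold higher, but is uncertain because it can share reads with the readthrough gene POC1B-GALNT4. Its call (adjusted p = 0.0367) was lost without any library except treated wild-type 1 and 2 (adjusted p from 0.0518 to 0.141). Lower in the knock-in line were the glycosyltransferase GALNT14 (chromosome 2, 30910467 to 31155202; 14.71 ± 0.0543 to 0.1245 ± 0.0601 CPM, −6.89 ± 0.46, adjusted p = 7.23e-05), the peroxidase PXDN (−5.93 ± 0.42), the kinase SYK (−5.37 ± 0.73, and −10.82 without untreated knock-in library 2) and the stem cell marker PROM1 (52.75 ± 13.8 to 1.51 ± 0.01 CPM, −5.12 ± 0.26). NFIB (−4.57 ± 0.35), CEMIP (−4.09 ± 0.41), MECOM (−4.05 ± 0.22) and HAS3 (129.7 ± 23.3 to 8.913 ± 0.309 CPM, −3.86 ± 0.17) were lower too.

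MYC was lower in untreated knock-in cells, at 98.73 ± 8.91 against 259 ± 80.6 CPM (−1.39 ± 0.19, edgeR quasi-likelihood, adjusted p = 0.00356). So were the immediate early genes FOSB (−1.87 ± 0.22, 0.00178) and EGR1 (−1.43 ± 0.18, 0.00222), the hypoxia-responsive ANGPTL4 (−2.10 ± 0.25, 0.00178) and the hexokinase HK2 (−1.39 ± 0.16, 0.00178). MVK, an enzyme of cholesterol synthesis, was lower (−1.39 ± 0.21, adjusted p = 0.00591, but 0.0589 without untreated knock-in library 2). Among genes of the unfolded protein and integrated stress response, CHAC1 was higher by 1.88 ± 0.24 (adjusted p = 0.00253), the cystine transporter SLC7A11 by 1.62 ± 0.16 (0.000752), PHGDH by 1.22 ± 0.19 (0.00565) and XBP1 by 1.04 ± 0.14 (0.00343). BMP4 (1.60 ± 0.14), PLK2 (1.49 ± 0.12) and DKK1 (1.45 ± 0.13) were higher, as were FN1 (2.10 ± 0.25), TAGLN (1.89 ± 0.21) and ICAM1 (1.33 ± 0.15, adjusted p = 0.00139). Among interferon genes, IFIT1 was higher (1.14 ± 0.19, adjusted p = 0.0094, but 0.0511 without untreated knock-in library 1). IRF1 (−0.08, 0.799), HLA-B (−0.27, 0.354), TAP1 (−0.57, 0.192), CD274 (0.08, 0.912) and MX1 (−0.31, 0.59) were not called. CDK19, the paralogue of CDK8, was higher by 0.83 ± 0.17 (adjusted p = 0.0227), a call lost without untreated wild-type library 1 (0.058), untreated knock-in library 1 (0.112) or treated knock-in library 1 (0.0546) or 2 (0.055). CDK8 (−0.37, 0.138), CCNC (0.27, 0.271), MED13 (0.17, 0.455) and AXIN2 (−0.15, 0.618) were not called. With the GC trend removed, CDK8 was called lower (−0.43, adjusted p = 0.0471). MED13L was lower (−0.82 ± 0.13, adjusted p = 0.00743), but not called without untreated knock-in library 2 (−0.69, 0.0644). IRF9 (0.82 ± 0.20, adjusted p = 0.0364) lost its call without any library except untreated wild-type 2 and untreated knock-in 1 (0.0527 to 0.219). CDKN1A (−0.49 ± 0.13, 0.0469) lost its call without any except untreated wild-type 2 (0.0967 to 0.228).

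In all, 1392 genes differed between the untreated lines, 703 higher and 689 lower in the knock-in line (316 and 303 by 2-fold or more), and 150 higher and 517 lower under spike-in scaling. GC content correlated with this difference at −0.36 (Spearman), and 2457 genes were called with the trend removed. The immunoglobulin signal was uneven between these groups (211 and 258 CPM in wild-type, 0.612 and 200 in knock-in cells). Genes that move with it may therefore enter the count. The count depended on the libraries and was 822 without untreated wild-type library 1, 4815 without untreated wild-type library 2 and 791 without either treated wild-type library 1 or 2. It was 534 without untreated knock-in library 1, 406 without untreated knock-in library 2, 645 without treated knock-in library 1 and 654 without treated knock-in library 2. Recovery of simulated changes was 46.9% at 2-fold and 77.7% at 4-fold.

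Tested as lists without treatment, MYC targets were lower in the knock-in line (median −0.46, 8 of 25 lower, 13 adjusted over the list alone; camera, adjusted p = 7.89e-05, but adjusted p = 0.141 with an estimated correlation). Fatty acid synthesis genes were lower too (−0.50, 4 of 13 lower, 8 over the list alone; camera, adjusted p = 0.00537, but adjusted p = 0.343 with an estimated correlation), at −0.33 with the GC trend removed. The unfolded protein and integrated stress response was higher (0.36, 9 of 23 higher, 10 over the list alone; camera, adjusted p = 3.89e-04, but adjusted p = 0.141 with an estimated correlation). The IFN-γ core list was higher (0.31, 6 of 50 higher and 2 lower, 10 and 4 over the list alone; camera, adjusted p = 0.00537, but adjusted p = 0.142 with an estimated correlation), at 0.50 without untreated wild-type library 2 and 0.16 without untreated knock-in library 1. Cholesterol biosynthesis was lower (−0.30, 8 of 25 lower; camera, adjusted p = 0.00999, but adjusted p = 0.222 with an estimated correlation) and not called without untreated wild-type library 2 (−0.07, 0.119). Immediate early genes were lower (−0.46, 7 of 24 lower and 1 higher, 11 and 3 over the list alone; camera, adjusted p = 0.00999, but adjusted p = 0.81 with an estimated correlation) and not called without untreated wild-type library 1 (−0.29, 0.0755), with −0.24 left after the GC trend was removed. Hypoxia genes were lower (−0.45, 7 of 24 lower and 2 higher, 10 and 3 over the list alone; camera, adjusted p = 0.0233, but adjusted p = 0.222 with an estimated correlation) and not called without untreated wild-type library 2 (−0.32, 0.119).

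Glycolysis genes were lower without treatment (−0.33, 4 of 21 lower and 1 higher, 8 and 1 over the list alone; camera, adjusted p = 0.0303, but adjusted p = 0.498 with an estimated correlation), at −0.17 without untreated wild-type library 1, −0.58 without untreated wild-type library 2 and not called without untreated knock-in library 1 (−0.37, 0.0867) or with the GC trend removed (−0.14, 0.0714). Fibroblast and stromal markers were higher (0.75, 2 of 8 higher; camera, adjusted p = 0.0233, but adjusted p = 0.231 with an estimated correlation), at 0.38 without untreated knock-in library 1, 1.24 without untreated knock-in library 2 and not called without untreated wild-type library 1 (0.41, 0.0572) or 2 (1.21, 0.121). Ribosomal protein mRNAs were higher under TMM (0.13, no gene called; camera, adjusted p = 0.0245, but adjusted p = 0.821 with an estimated correlation) and lower under spike-in scaling (−0.19). They stood at 0.30 without untreated wild-type library 2 and 0.19 without untreated knock-in library 1, and were not called without untreated wild-type library 1 (0.01, 0.708) or untreated knock-in library 2 (0.08, 0.25). MHC class I (adjusted p = 0.814), type I interferon-stimulated genes (0.193) and mesenchymal markers (0.415) were not called, nor were mitochondrially encoded mRNAs (−0.24, 0.175, but −0.55 and 0.021 with the GC trend removed).

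The fifth comparison asked how the lines differed with IFN-γ. SPARC was at least 82.1-fold higher in treated knock-in cells, ANKRD1 higher by 6.68 ± 0.42 (edgeR quasi-likelihood, adjusted p = 6.29e-05) and CAVIN2, a caveolar protein, by a ratio of 87.2 (95% counting interval 29.5 to 425; log2 value 9.90 without treated wild-type library 1). FAM50B was higher by 6.15 ± 0.77, MAGEB1 by 5.64 ± 0.25, MUC13 by 5.01 ± 0.52 and SLC2A3 by 4.75 ± 0.18. GALNT14 (−6.56 ± 0.42), PROM1 (−5.53 ± 0.28), SYK (−5.00 ± 0.66), PXDN (−4.91 ± 0.36), MECOM (−4.55 ± 0.23), NFIB (−4.07 ± 0.33) and HAS3 (−3.22 ± 0.16) were lower. Among interferon genes, the adhesion molecule ICAM1 was higher, at 137.5 ± 0.757 against 40.76 ± 0.919 CPM (1.75 ± 0.13, adjusted p = 0.000167). IRF1 (−0.02, 0.973), IRF9 (0.56, 0.169), GBP1 (0.22, 0.609), IDO1 (0.38, 0.532), HLA-B (−0.21, 0.619), TAP1 (−0.22, 0.734), CIITA (0.14, 0.909), CD274 (−0.14, 0.891), SOCS1 (0.15, 0.931), IFIT1 (0.31, 0.483) and MX1 (0.52, 0.472) were not called. CHAC1 remained higher (2.05 ± 0.24, adjusted p = 0.00196), with BMP4 (1.40 ± 0.13), DKK1 (1.42 ± 0.13), TAGLN (1.64 ± 0.21) and TGFB2 (4.63 ± 0.61). MYC was no longer called (−0.62 ± 0.19, adjusted p = 0.144; 402 ± 2.84 and 262.2 ± 2.87 CPM), nor were CDK8 (−0.37, 0.248), CDK19 (0.60, 0.117), CCNC (−0.06, 0.909), MED13 (−0.15, 0.671), CDKN1A (−0.22, 0.452) or AXIN2 (0.01, 0.99). MED13L was lower (−0.67 ± 0.13, adjusted p = 0.0283), but not called without treated wild-type library 1 (0.189) or 2 (0.213), treated knock-in library 1 (0.267) or 2 (0.252), or under spike-in scaling (−0.73, 0.157). TM7SF2, an enzyme of cholesterol synthesis, was lower (−1.12 ± 0.18, adjusted p = 0.00961), but not called without treated wild-type library 2 (0.104) or treated knock-in library 1 (0.127) or 2 (0.128).

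In all, 481 genes differed with IFN-γ, 269 higher and 212 lower in the knock-in line (181 and 129 by 2-fold or more), and 95 higher and 100 lower under spike-in scaling. GC content hardly correlated with this difference (0.08), and 1292 genes were called with the trend removed. The immunoglobulin signal was uneven here too (1.3 and 0.326 CPM in wild-type, 0.879 and 165 in knock-in cells), so its genes may enter the count. The count was 1015 without untreated wild-type library 1, 1111 without untreated wild-type library 2, 189 without treated wild-type library 1, 147 without treated wild-type library 2, 147 without treated knock-in library 1 and 155 without treated knock-in library 2. Recovery of simulated changes was 48% at 2-fold and 79.8% at 4-fold. Cholesterol biosynthesis was lower (median −0.48, 5 of 25 lower, 13 and 1 higher over the list alone; camera, adjusted p = 3.07e-07, but adjusted p = 0.0597 with an estimated correlation). Fatty acid synthesis was lower too (−0.38, 3 of 13 lower, 6 over the list alone; camera, adjusted p = 2.72e-05, but adjusted p = 0.163 with an estimated correlation). The unfolded protein and integrated stress response was higher (0.44, 5 of 23 higher, 8 over the list alone; camera, adjusted p = 1.31e-06, but adjusted p = 0.0597 with an estimated correlation). Fibroblast markers were higher (1.22, 1 of 8 higher, 3 over the list alone; camera, adjusted p = 2.47e-04, but adjusted p = 0.129 with an estimated correlation), and so were mesenchymal markers (0.57, 6 of 22 higher and 2 lower, 8 and 2 over the list alone; camera, adjusted p = 0.00127, but adjusted p = 0.189 with an estimated correlation).

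The IFN-γ core list was higher with IFN-γ by a median of 0.17 (1 of 50 higher; camera, adjusted p = 0.00852, but adjusted p = 0.143 with an estimated correlation), not called without treated wild-type library 1 (0.20, 0.0534) or treated knock-in library 1 (0.13, 0.0903). Type I genes were higher by 0.23 (3 of 47 higher and 1 lower; camera, adjusted p = 0.0171, but adjusted p = 0.309 with an estimated correlation), not called without treated wild-type library 1 (0.19, 0.0611) or 2 (0.25, 0.0617) or treated knock-in library 1 (0.17, 0.0608). Ribosomal protein mRNAs were higher by 0.19 with no gene called (camera, adjusted p = 1.99e-04, but adjusted p = 0.818 with an estimated correlation), not called without treated wild-type library 1 (0.13, 0.0633). MYC targets were lower by −0.15 with no gene called (camera, adjusted p = 0.0153, but adjusted p = 0.163 with an estimated correlation), not called without treated wild-type library 2 (−0.16, 0.0986) or treated knock-in library 1 (−0.15, 0.0664). Heat shock proteins were lower by −0.25 (camera, adjusted p = 0.0219, but adjusted p = 0.358 with an estimated correlation), not called without treated wild-type library 1 (−0.29, 0.0604) or 2 (−0.25, 0.0824) or treated knock-in library 2 (−0.20, 0.0916). Hypoxia (adjusted p = 0.0951) and immediate early genes (0.193) were not called.

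**Figure D4:**
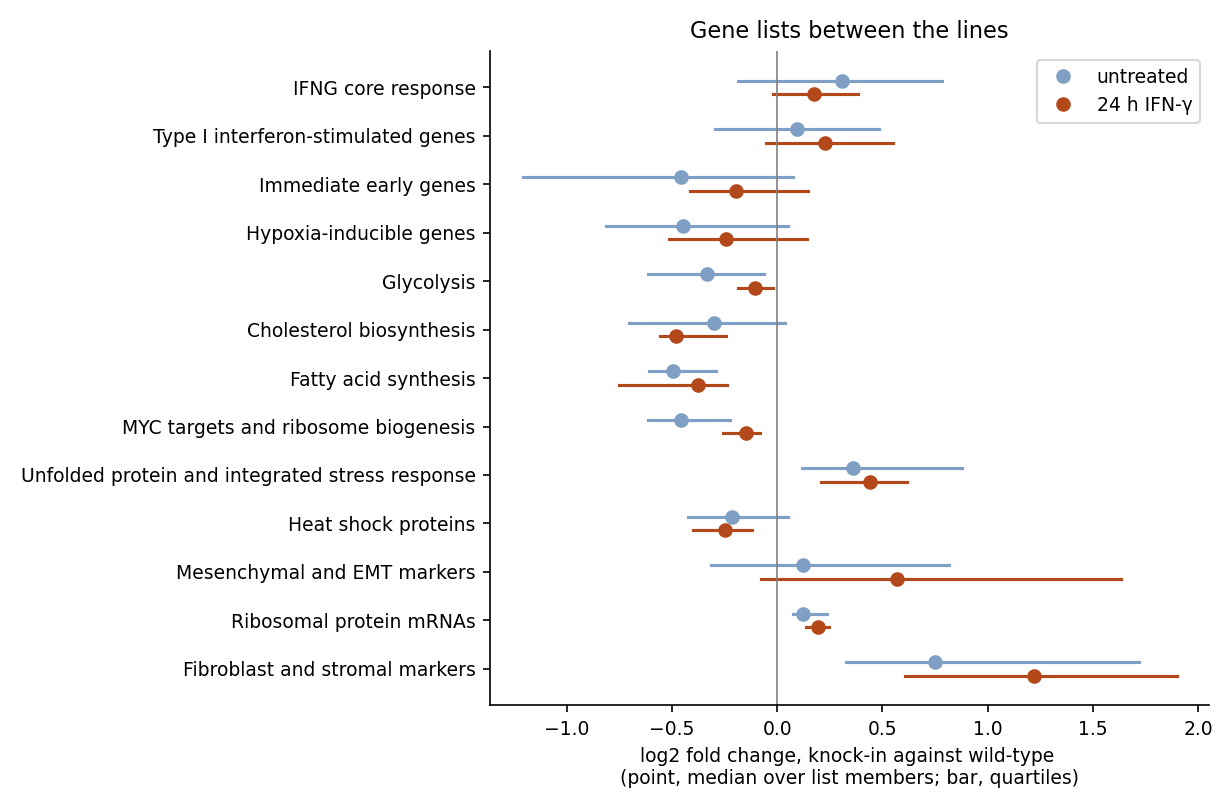
Log2 fold change of the knock-in against the wild-type line for the members of 13 gene lists, without treatment (blue) and after 24 h of IFN-γ (red), with points at the median and bars over the quartiles. Cholesterol biosynthesis lay at −0.30 and −0.48 and the unfolded protein and integrated stress response at 0.36 and 0.44, while spike-in scaling moved the untreated ribosomal protein mRNAs to −0.19 and mesenchymal markers to −0.20.

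The line differences persisted across treatments. Both comparisons called 210 genes higher (11.4 expected from the counts) and 167 lower (8.8 expected) in the knock-in line, SLC2A3 and GALNT14 among them, and 0 went opposite ways (Pearson correlation 0.277). Averaged over treatments, 2291 genes differed, 1156 higher and 1135 lower (386 and 233 by 2-fold or more), and 391 higher and 1091 lower under spike-in scaling. This count was 4809 without untreated wild-type library 2, 1112 and 1165 without treated wild-type library 1 and 2, 1308 without untreated knock-in library 2, and 972 and 922 without treated knock-in library 1 and 2. Recovery of simulated changes was 69.4% at 2-fold and 88.3% at 4-fold.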

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

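Of the tests in this part, those on the spike-in spread, on the size of the response without untreated wild-type library 1 and on the splits of the libraries were written before their results were seen. Those on GC content, histones, genes outside the interferon lists, plasma cell markers, the IGHA1 to JCHAIN ratio, the immunoglobulin ratio between replicates and the line splits with treatment as a term were written after the pattern had been seen.

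MYC targets stood out because their IFN-γ response differed between the lines by a test of the difference itself, with a median log2 difference of 0.19 (camera, adjusted p = 0.0403, but adjusted p = 0.684 with an estimated correlation and 0.0809 with fry), although no single gene was called. The call was lost without untreated wild-type library 2 (adjusted p = 0.25), treated wild-type library 1 (0.256), untreated knock-in library 1 (0.0599) or treated knock-in library 1 (0.0718) or 2 (0.101). Genes raised by 2-fold or more on average had a median knock-in minus wild-type response of 0.36 (camera p = 1.67e-08, but p = 0.314 with an estimated correlation) and lowered genes one of −0.21 (camera p = 9.24e-11, but p = 0.395 with an estimated correlation). Without untreated wild-type library 1 these were 0.06 and −0.01, neither called by camera, and spike-in scaling gave 0.05 for lowered genes. The ERCC spike-ins, which no comparison of genes used, made up a larger share of counts in treated libraries of the wild-type (0.249%) and the knock-in line (0.263%) than in untreated ones (0.119% and 0.139%).

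The larger response of raised genes in the knock-in line fits a difference in base composition between libraries. With the GC and length trend removed, the excess was 0.06 over 799 genes, against 0.36 over 1622 genes in the main fit. Without untreated wild-type library 1 it was also 0.06. Other exclusions enlarged it, to 0.60 without untreated knock-in library 1 and 0.62 without that library and treated knock-in library 2. In the last of these fits the immunoglobulin signal was alike in both lines. The genes were chosen anew in each fit, so the values are not over the same genes. Removal of the trend and exclusion of untreated wild-type library 1 are not independent tests, since that library has the highest GC content of the untreated ones. A true but small difference in response size could be removed by the same correction, so biology is not excluded.

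Of the 9665 genes called in the mean response, 55.2% (5335) kept their call and direction with the GC and length trend removed. The trend as fitted therefore does not account for the whole response. Its removal was not complete, as GC content still correlated with the change at 0.13 in wild-type and 0.11 in knock-in cells. A part of the kept calls may thus still follow GC content. The spread of spike-in ratios between treated and untreated libraries was 2.48 times that given by replicate differences (21 spike-ins, SD 0.406 against 0.164), which fits a bias of library preparation that also acts on RNA the cells never made. The log2 changes of all tested genes in the mean response had an SD of 1.06, low-count genes included. Lower histone mRNAs fit the GC and length trend by their median, which went from −0.88 to −0.10 (14 genes). With the trend removed, 5 of them were called lower, against 8 before, and the quartiles were −0.52 and 0.42. The trend as fitted therefore does not account for every fall among histones. Outside the interferon lists, 40.8% of tested genes (6681 of 16375) were called after the removal, against 9544 before. Not all of the 6681 had been called in the same direction before. These data cannot tell a batch that follows the treatment, or time in culture, from a broad effect of IFN-γ.

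With the libraries compared as 4 against 4, only 1 of 35 splits, the treatment itself, gave as many calls as it did (8219, against 224 for the next). Every other split holds treated and untreated libraries on each side without a treatment term, so a treatment difference itself lowers their counts. As 1 of 35 is the smallest share these splits allow, an accidental grouping is not excluded. For the line split, with 224 calls, the 1 other split to reach its count was the treatment split, a structure of the design, so 2 of 35 decides nothing there. The highest of the 33 splits other than line and treatment had 69, the split by immunoglobulin counts. With treatment as a term and 2 untreated and 2 treated libraries on each side, the line split called 2081 genes and the highest other 0, in 18 splits, which are too few for a share under 0.05.

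Immunoglobulin transcripts stood at 165 to 258 CPM in 4 libraries and at 1.3 or below in the other 4. An effect of line or treatment would act alike on replicates, but the counts differed up to 444-fold between replicates of a group. RNA or reads of plasma cells would bring other plasma cell genes, and 80% of detected plasma cell markers other than immunoglobulin genes and JCHAIN (12 of 15) were at least 4 times higher in those libraries. SDC1 (317 against 67.7 CPM) exceeded IGKC (73.6 CPM), so the kind of cell stays open. The IGHA1 to JCHAIN ratio varied 1.58-fold among the 4 libraries (0.37, 0.57, 0.36 and 0.51), which cannot tell a single source from several. The IGKC to JCHAIN ratio, for which no prediction was written, varied less (0.47, 0.55, 0.49 and 0.48 in the same order).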

How the results depend on the processing

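The analysis and most alternatives were fixed before the data were examined; the GC and length trend, spike-in scaling and the exclusions by immunoglobulin counts were chosen after seeing the data. With 1 library left in a group, that library is assumed to vary like the others. Named genes kept their side of the threshold, and called ones their direction, in 5460 of 6062 settings (554 weaker, 35 stronger, 13 reversed). Lists did so in 1891 of 2030 (73 weaker, 65 stronger, 1 reversed). Direction was not compared for results not called in the main fit, nor for lists with fry or an estimated correlation. Fits with only the 2 groups compared do not apply to the difference, mean and size results, nor blocks within line to line differences. Unless stated, the cause was not tested.

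Against 1.5-fold (glmTreat), a stricter question, calls numbered 1921 for the wild-type response, 4693 for the knock-in response, 250 and 160 for the line difference without and with IFN-γ, 4495 for the mean response and 366 for the mean line difference. With the GC and length trend removed they were 3970, 4992, 2457, 1292, 6797 and 3866, and the size of the response was 0.06 for raised and −0.09 for lowered genes. Spike-in scaling gave 667 and 195 for the line differences and 1482 for their mean, with size 0.40 (no longer called) for raised and 0.05 (reversed) for lowered genes. DESeq2 gave 2202 and 832 for the line differences and 4 for the difference between responses. With no filter the line differences were 2959 and 1227, their mean 3502 and the difference between responses 267. With only the groups compared, line differences were 614 and 2427. Without untreated knock-in 1 and treated knock-in 2 together, fewer libraries gave 5194 for the knock-in response, 189 and 122 for the line differences and 564 for their mean, and 0.62 for the size of raised genes. Without both knock-in libraries of number 1 or 2, the knock-in response had 5048 or 3523.

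Leaving out single libraries gave 3266 to 7796 for the wild-type response, 6327 to 9322 for the knock-in response, 406 to 4815 and 147 to 1111 for the line differences, 0 to 2 for the difference between responses, 8349 to 10191 for the mean response, 922 to 4809 for the mean line difference, and 0.06 to 0.60 and −0.42 to −0.01 for the size of raised and lowered genes.

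Spike-in scaling shifts most genes by a like amount (quartiles −0.82 to −0.78 for the wild-type response) and reversed, in wild-type cells, NFKB2 (−0.08), SRF (−0.06), MED13L (−0.12), MYC (−0.21), KRT8 (−0.25), KRT19 (−0.36), AEN (−0.02), MED12 (−0.08) and TNFAIP2 (−0.10), in knock-in cells RFX5 (−0.10), and between untreated lines the ribosomal protein list (−0.19). Removal of the GC trend reversed MED21 in wild-type (0.01) and HPRT1 (0.16) and CXCL8 (0.48) in knock-in cells.

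With the replicate block, calls were 6765, 8725, 1849, 523, 0, 9779 and 2601 in the order wild-type response, knock-in response, line difference without and with IFN-γ, difference between responses, mean response and mean line difference, with sizes 0.37 and −0.21. A replicate block within line gave 27 for the difference between responses. Deviations of same-numbered libraries from their group means correlated at −0.002 to 0.074, and at 0.27 between the knock-in groups. The second libraries of both knock-in groups carry the immunoglobulin counts. The numbers thus show no pairing over all groups, but a pairing within the knock-in line was not tested and stays open. Of simulated 2-fold differences between responses, 15.5% were recovered. Depth was not varied, and replicates differed by more than counting error (chi-square per gene 7.17 to 55.3), while for genes at 0 depth sets the bounds, at 3 counts per library.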

Other observations

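VIM stood at 24.81 and 30.2 CPM in untreated wild-type, 4.461 and 3.223 in treated wild-type, 21.94 and 40.52 in untreated knock-in and 18.27 and 38.2 in treated knock-in libraries. TXNIP stood at 8.5 and 7.76 CPM in untreated wild-type, 7.63 in untreated knock-in library 2 and 2.23 in treated knock-in library 2, and at 0 elsewhere. Among libraries without the immunoglobulin signal, VIM was thus higher in the knock-in line. Replicates of untreated wild-type differed most, with a median difference of 0.388 on the log2 scale, against 0.173 in treated wild-type, 0.228 in untreated knock-in and 0.127 in treated knock-in.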
